A study of Saccharomyces cerevisiae with 10 samples.

How the data were processed

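Gene expression of 5 genotypes of haploid S. cerevisiae, 2 cultures each, was read on 10 Affymetrix arrays, 1 per culture. The authors normalized the intensity values in Affymetrix Expression Console, version not given, and the deposited table holds 1 value per probe set and array. The algorithm and the scaling are not given in the sources used here. The values were on a linear scale, since they ran from 0.00517 to 3479 with array medians from 9.45 to 11.0. They were therefore used as log2 of the value plus 16, which shrinks the differences of dim genes. A 2-fold change in the text is one of the value plus 16, and the number of such changes depends on the 16.

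Of 10928 probe sets in the table, 7244 named 1 gene, 1 named several and 3683 had no gene entry, of which 166 were Affymetrix controls. Another 1746 of the named ones belonged to another species, and 5498 named 1 S. cerevisiae gene. For 47 genes with several probe sets the brightest was used, which left 5449 genes. Among the calls, 21 pairs of gene and comparison had probe sets with opposite signs. Of the tested probe sets, 114 have names that mark possible reading of related genes, and such genes are called shared in the text. The background limit was the 95th percentile of the probe sets of the other species, 4.15 on the log2 scale or an intensity of 1.73. Gene symbols and neighbour order came from the annotation of the R64 assembly, and the authors' genome build is not given in the sources used here.

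No array was left out. The limma package 3.58.1 in R 4.3.3 fitted 1 mean per genotype to all 10 arrays, with moderated variances and two-sided Benjamini-Hochberg adjusted p under 0.05 for a call. Because the fit pools the spread of all genotypes, each comparison borrows precision from the arrays it does not compare. The comparisons were each of the 4 strains with evolved alleles against ancestral, MDS3e MKT1e against each strain with 1 of its alleles, PMA1e MKT1e against MKT1e and against MDS3e MKT1e, and the interaction of MDS3e and MKT1e. Because the strains compared with ancestral share its 2 arrays, no overlap among those comparisons is given. The limma F-test asked whether a gene differed among the 5 genotypes.

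Fixed gene lists, 29 in number, were tested with limma's camera at a preset correlation of 0.01 between genes, adjusted over the 261 tests of lists and comparisons. Each list was also tested with the correlation estimated from the data and with fry, and its members were adjusted over the list alone. Only the mitochondrial ribosomal protein list was called with an estimated correlation in any comparison. The mitochondrial ribosomal protein, cytosolic ribosomal protein and proteasome lists took genes by a pattern in their symbols, so a member can be misnamed. Chromosome medians and windows of 9 neighbouring genes were computed from the same differences.

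The comparisons, tests, gene lists, alternatives and the rule for naming genes were fixed before the data were examined. The rule took the 3 evolved genes, the 10 largest rises and the 10 largest falls per comparison among genes that passed the test and whose arrays did not overlap between the genotypes, and up to 4 members of each list that changed. It gave 837 pairs of gene and comparison, of which 776 passed the test, and 528 of those kept their call whichever array was left out, while 248 lost it at least once. The text names fewer genes than the rule gave. Those named were mostly taken from the ones that kept their call when arrays were left out or rescaled, a choice made after the values were seen, so the named genes are steadier than the average called gene.

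The range of the array medians over S. cerevisiae genes was 0.105 on the log2 scale. That exceeded the 0.1 set beforehand, so counts after median centring of each array are given beside the main counts. The other alternatives were quantile normalization, pseudocounts of 1 and 64, leaving out genes below background or shared probe sets, the mean of all probe sets of a gene, trended and robust variances, array weights, only the compared genotypes, a replicate block, stricter thresholds and leaving out each array in turn. Cyclic loess between arrays, a block with exchanged replicate numbers and gene lists with each array left out, 2-fold counts with other pseudocounts and the nearest genes by level of each ribosomal protein gene were added after results had been seen.

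The limma steps were tested on simulated data with the measured means and spreads of 5449 genes, in 20 simulations with 200 changed genes each. Recovery was 61.1% at 1.25-fold, 93.6% at 1.5-fold, 99.3% at 2-fold and 100% at 4-fold, with 4.53% false calls and 0 calls in the wrong direction. A list shifted by 0.3 on the log2 scale was recovered in 20 of 20 simulations. The simulated genes were independent of each other, so this did not test the camera results against correlated genes.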

Results

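Messenger RNA was measured on 10 Affymetrix yeast arrays, 1 for each of 10 cultures of haploid Saccharomyces cerevisiae. The 5 genotypes shared 1 genetic background and differed in which evolved alleles they carried. They were the ancestral strain without evolved alleles, MKT1e, MDS3e, MDS3e MKT1e and PMA1e MKT1e, where e marks the evolved allele of the named gene. MKT1 encodes a protein of post-transcriptional mRNA regulation, MDS3 a component of nutrient signalling and PMA1 the proton pump of the plasma membrane. Replicates are labelled biological and came from separate cultures, with n = 2 arrays per genotype. Cells grew overnight in rich medium and then in defined medium with 0.25% dextrose until the culture reached an optical density of about 0.2, after about 17 h. No strain with the evolved PMA1 allele alone was analysed here.

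Of the 5449 S. cerevisiae genes tested, between 5358 and 5379 lay above the background limit on each array. Replicate arrays correlated with Pearson's r from 0.996 to 0.998 across genes, which are not independent replicates, and the median SD between the 2 arrays of a genotype ran from 0.04 to 0.06 on the log2 scale. Arrays of different genotypes correlated with r from 0.973 to 0.998. With limma's moderated F-test, 2998 genes (55.0%) differed among the genotypes. The number of arrays limits the precision, and a difference between 2 genotypes had a median standard error of 0.07. The ancestral arrays had the largest median SD, 0.064, against 0.037 for PMA1e MKT1e. The pooled fit gives a gene the same standard error in each comparison of 2 genotypes, so precision against ancestral may be overstated. Differences are log2 differences ± SE with 2 arrays in each genotype, and adjusted p is limma's after Benjamini-Hochberg adjustment. For every gene taken by rule for the size of its change between 2 genotypes, both arrays of one genotype lay above both arrays of the other. Where an array was left out, the lone array of that genotype was assumed to vary like the other genotypes.

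The evolved genes themselves were read first. For a strain's own evolved gene, the values cannot tell a change in mRNA amount from a difference in how probes read the evolved allele. The mean log2 level of MKT1 was 8.93 ± 0.28 (SD, n = 2) in ancestral cells, 8.58 ± 0.10 in MKT1e, 9.03 ± 0.01 in MDS3e, 8.81 ± 0.01 in MDS3e MKT1e and 8.58 ± 0.03 in PMA1e MKT1e. MKT1 fell by 0.35 ± 0.11 in MKT1e (adjusted p = 0.039) and by 0.35 ± 0.11 in PMA1e MKT1e (adjusted p = 0.037). The first call was lost without any 1 of the arrays except Ancestral replicate 2, and the value was -0.15 (adjusted p = 0.19) without Ancestral replicate 1 and -0.55 without Ancestral replicate 2. The second was lost in 7 of the 10 runs that left out an array, with -0.15 (adjusted p = 0.18) without Ancestral replicate 1 and -0.55 without Ancestral replicate 2. MDS3 differed from ancestral by -0.16 ± 0.06 in MDS3e (adjusted p = 0.062) and by -0.11 ± 0.06 in MDS3e MKT1e (adjusted p = 0.18), but after median centring it passed the test in both, at -0.22 (adjusted p = 0.017) and -0.19 (adjusted p = 0.021). PMA1 had a mean log2 level of 11.19 ± 0.04 in ancestral cells, 11.18 ± 0.00 in MKT1e, 10.83 ± 0.04 in MDS3e, 10.76 ± 0.01 in MDS3e MKT1e and 11.14 ± 0.02 in PMA1e MKT1e. PMA1 fell by 0.37 ± 0.05 in MDS3e (adjusted p = 0.0012), and the value was -0.14 (adjusted p = 0.072) after quantile normalization and -0.15 (adjusted p = 0.061) after cyclic loess. It fell by 0.43 ± 0.05 in MDS3e MKT1e (adjusted p = 0.00013), and the value was -0.16 (adjusted p = 0.03) after quantile normalization and -0.18 (adjusted p = 0.023) after cyclic loess.

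The evolved MKT1 allele alone was accompanied by higher mRNA of the mitochondrial ribosome. Many genes of the respiratory chain were higher and many under nitrogen catabolite repression lower, but neither list was called with an estimated correlation (adjusted p = 0.19 and 0.11). Of 73 mitochondrial ribosomal protein genes, 70 rose and 3 did not pass the test, with a median log2 difference of 0.66. MRPL4 rose by 1.12 ± 0.06, MRPS35 by 0.96 ± 0.07, RSM28 by 0.94 ± 0.05 and MRPL1 by 0.94 ± 0.06. Adjusted over the list alone, 72 rose and 1 fell. Since the list was drawn by symbol, a member that fell, here or in other comparisons, need not encode a mitochondrial ribosomal protein. The camera test gave adjusted p = 2.4e-50, and adjusted p = 0.0079 with an estimated correlation.

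Of 38 genes of the respiratory chain and ATP synthase, 23 rose, 1 fell and 14 did not pass, and adjusted over the list alone 32 rose and 1 fell. CYC1, the aerobic isoform of cytochrome c, rose by 1.94 ± 0.08. The mitochondrial NADH dehydrogenase genes NDE1 and NDI1 rose by 0.93 ± 0.05 and 0.78 ± 0.08, and CYT1, cytochrome c1 of complex III, by 0.66 ± 0.08. The median was 0.30 with a camera adjusted p = 1.7e-13, and adjusted p = 0.19 with an estimated correlation. Outside that list, the cytochrome oxidase assembly factor COA2 rose by 1.17 ± 0.07, and SDH2, a subunit of succinate dehydrogenase, by 0.56 ± 0.06.

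Of 27 genes under nitrogen catabolite repression, 14 fell, 1 rose and 12 did not pass in MKT1e. Among them DAL5 fell by 1.67 ± 0.07, DAL80 by 1.52 ± 0.12, DAL7 by 1.32 ± 0.07 and DAL4 by 1.16 ± 0.09. DAL5 and DAL4 encode the allantoate and allantoin permeases, DAL7 a malate synthase and DAL80 a GATA-type repressor. The list's median was -0.21 (camera adjusted p = 5.2e-07), with adjusted p = 0.11 with an estimated correlation, and adjusted over the list alone 15 fell and 1 rose. The peptide transporter gene PTR2 fell by 1.15 ± 0.09 and the acidic amino acid permease gene DIP5 by 1.08 ± 0.18.

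Pheromone response genes rose in 10 of 23 cases with none falling (adjusted over the list alone, 12 rose), among them AGA1 by 0.87 ± 0.07, PRM1 by 0.83 ± 0.13 and FUS1 by 0.64 ± 0.08. Their median was 0.21 (camera adjusted p = 1.4e-05), with adjusted p = 0.11 with an estimated correlation. HO, the endonuclease gene of mating-type switching, whose mRNA is a known target of Mkt1, rose by 0.41 ± 0.07. Of 51 general stress genes, 18 rose, 4 fell and 29 did not pass (19 and 6 adjusted over the list alone). The small heat shock protein gene HSP26 rose by 1.15 ± 0.12, the catalase gene CTT1 by 1.10 ± 0.09 and the hydrophilin gene SIP18 by 1.05 ± 0.13. The list's median was 0.07 (camera adjusted p = 0.0039), with adjusted p = 0.52 with an estimated correlation.

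Single genes with large rises in MKT1e were the membrane protein gene YRO2 by 2.00 ± 0.12, the transketolase gene TKL2 by 1.29 ± 0.09 and YHB1, which encodes the flavohaemoglobin that detoxifies nitric oxide, by 1.24 ± 0.08. IMD2, an IMP dehydrogenase gene of guanine nucleotide synthesis whose probe set can also read its close copies, fell by 2.80 ± 0.10. Its relative IMD3 fell by 0.39 ± 0.05. The glucose-repressed alcohol dehydrogenase gene ADH2 fell by 1.14 ± 0.07, and the mitochondrial dicarboxylate carrier gene DIC1 by 1.03 ± 0.06. In all, 1104 of 5449 genes changed, 642 higher and 462 lower, and 29 of them changed at least 2-fold. After median centring of each array 582 were higher and 637 lower, and without MKT1e replicate 2 the count was 676.

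With the evolved MDS3 allele alone, many genes of the phosphate regulon and of ribosome biogenesis were higher and many of the general stress response and of trehalose and glycogen metabolism lower. With an estimated correlation none of these lists was called (adjusted p = 0.23, 0.35, 0.16 and 0.24 in that order). Of 18 phosphate regulon genes, 13 rose, 2 fell and 3 did not pass, with the same numbers adjusted over the list alone. PHO89, a sodium and phosphate cotransporter gene, rose by 2.84 ± 0.10. The acid phosphatase genes PHO11, whose probe set is shared with a close copy, and PHO5 rose by 2.27 ± 0.15 and 1.54 ± 0.08. SPL2, a negative regulator of low-affinity phosphate transport, rose by 1.93 ± 0.14, and VTC3, a subunit of the polyphosphate synthase complex, by 1.39 ± 0.08. PHM7, a membrane protein gene of the same list, fell by 1.59 ± 0.09. The list's median was 0.72 (camera adjusted p = 8.9e-09), with adjusted p = 0.23 with an estimated correlation.

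Of 51 general stress genes, 39 fell in MDS3e and 12 did not pass, and adjusted over the list alone 43 fell and 1 rose. YGP1, a secreted glycoprotein gene of nutrient limitation, fell by 1.81 ± 0.08, DDR2 by 1.61 ± 0.08, the hexose transporter gene HXT5 by 1.21 ± 0.08 and MSC1 by 1.18 ± 0.06. CTT1 fell by 1.17 ± 0.09 and HSP26 by 1.15 ± 0.12. The median was -0.54 (camera adjusted p = 4.5e-27), with adjusted p = 0.16 with an estimated correlation. Of 20 trehalose and glycogen genes, 13 fell and 1 rose, also adjusted over the list alone. GAC1, which targets a phosphatase to glycogen synthase, fell by 1.02 ± 0.09, the glycogen phosphorylase gene GPH1 by 0.82 ± 0.06 and the trehalose synthase subunit gene TSL1 by 0.72 ± 0.07. Their median was -0.37 (camera adjusted p = 1.8e-09), with adjusted p = 0.24 with an estimated correlation.

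Of 100 ribosome biogenesis genes, 52 rose in MDS3e and none fell, and adjusted over the list alone 62 rose and 1 fell. The pre-rRNA processing genes UTP7, RRP15 and KRR1 rose by 0.70 ± 0.08, 0.68 ± 0.09 and 0.51 ± 0.09. The median was 0.23 (camera adjusted p = 3.9e-11), with adjusted p = 0.35 with an estimated correlation. Of 127 cytosolic ribosomal protein genes, 71 fell and 2 rose (82 and 3 adjusted over the list alone), with a median of -0.23 (camera adjusted p = 1.1e-17) that became -0.01 after quantile normalization, where the camera direction turned and the call was lost. With an estimated correlation the adjusted p was 0.23. RPS31 fell by 0.49 ± 0.06 and RPL40A by 0.41 ± 0.07, against -0.19 and -0.17 after quantile normalization. The 545 brightest genes as a whole had a median difference of -0.15 in MDS3e, against a range from 0.00 to 0.06 for the other 9 groups of genes by brightness.

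Of 20 glycolysis and fermentation genes in MDS3e, 14 fell and none rose (15 adjusted over the list alone), with a median of -0.27 (camera adjusted p = 8.4e-07) that was -0.09 after quantile normalization, where the call was lost, and with adjusted p = 0.37 with an estimated correlation. Of 9 histone genes, 3 fell with a median of -0.18 (camera adjusted p = 0.009, and adjusted p = 0.22 with an estimated correlation), and quantile normalization turned that median to 0.05. HTA1 fell by 0.42 ± 0.05, and the value was -0.11 (adjusted p = 0.22) after quantile normalization. Of 40 cell wall genes, 14 fell and 1 rose (15 and 1 adjusted over the list alone), among them PIR3 by 0.56 ± 0.08, TIP1 by 0.50 ± 0.09 and CWP1 by 0.50 ± 0.06. Their median was -0.16 (camera adjusted p = 3.7e-05), with adjusted p = 0.16 with an estimated correlation.

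Among other genes in MDS3e, YHB1 rose by 1.12 ± 0.08 and OPT2, an oligopeptide transporter gene, by 1.41 ± 0.08. The hexose transporter genes HXT2 and HXT4 rose by 0.95 ± 0.15 and 0.70 ± 0.07. YRO2 fell by 1.59 ± 0.12, FMP16 by 1.71 ± 0.08 and FMP45 by 1.38 ± 0.12. In all, 1375 genes changed, 790 higher and 585 lower, 27 of them at least 2-fold. After median centring 504 were higher and 845 lower. The count was 749 without Ancestral replicate 2, 554 without MDS3e replicate 1 and 623 without MDS3e replicate 2.

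**Figure D1:**
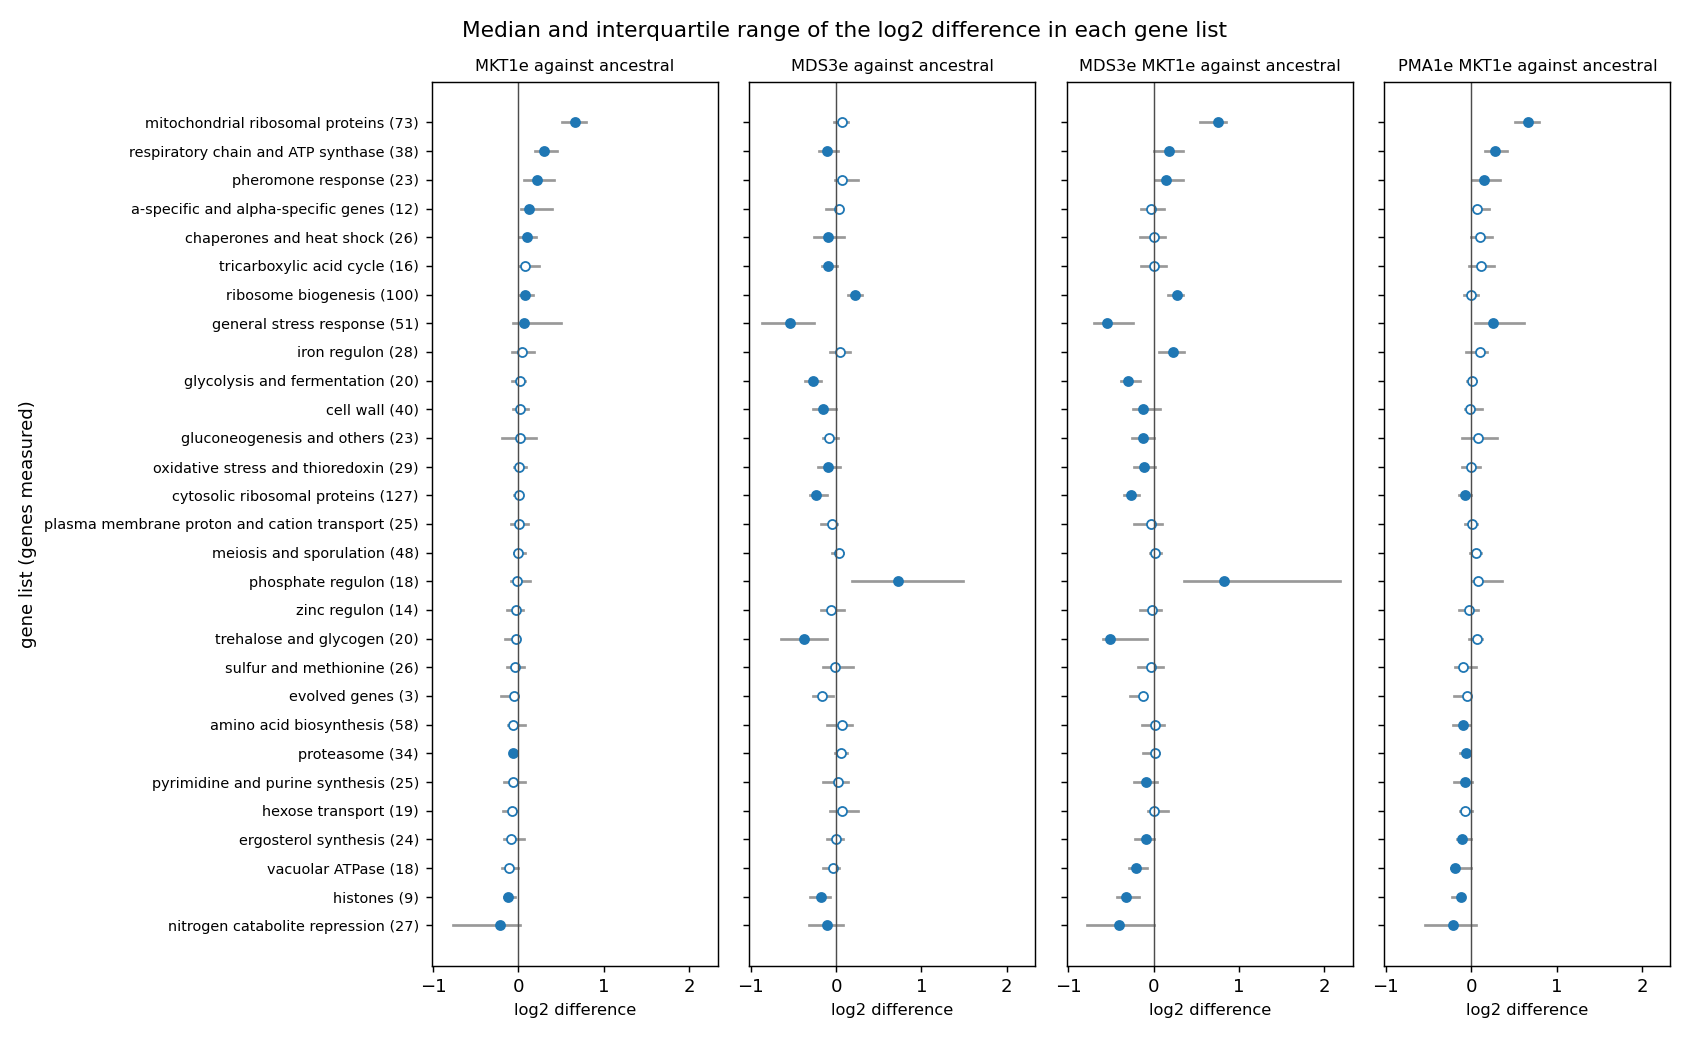
Median log2 difference (points) and interquartile range (bars) of fixed gene lists in each comparison against ancestral, drawn from 2 arrays per genotype. Filled points mark lists called by camera with the preset correlation of 0.01. Mitochondrial ribosomal proteins stand at 0.66 in MKT1e, and the phosphate regulon at 0.72 and general stress genes at -0.54 in MDS3e; the cytosolic ribosomal protein median of -0.23 in MDS3e became -0.01 after quantile normalization.

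The strain with both alleles, MDS3e MKT1e, was set against the ancestral strain. Mitochondrial ribosomal protein genes rose in 71 of 73 cases and 1 fell, with a median of 0.75 and camera adjusted p = 5e-35, and adjusted p = 0.012 with an estimated correlation. Adjusted over the list alone, 72 rose and 1 fell, and MRP21, MRPL24, MRPS35 and MRPL40 rose by 1.09 ± 0.10, 1.06 ± 0.06, 1.04 ± 0.07 and 1.04 ± 0.06. Phosphate regulon genes rose in 14 of 18 cases and 1 fell (15 and 1 adjusted over the list alone). PHO89 rose by 3.36 ± 0.10, PHO5 by 2.43 ± 0.08, PHM6 by 2.37 ± 0.11, SPL2 by 2.36 ± 0.14 and VTC4, of the polyphosphate synthase complex, by 1.24 ± 0.08. Their median was 0.82 (camera adjusted p = 2.8e-09), with adjusted p = 0.23 with an estimated correlation.

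General stress genes fell in 38 of 51 cases and 2 rose in MDS3e MKT1e (40 and 3 adjusted over the list alone), with a median of -0.55 (camera adjusted p = 1.3e-16) and adjusted p = 0.22 with an estimated correlation. The glutamate decarboxylase gene GAD1 fell by 1.28 ± 0.08, MSC1 by 1.26 ± 0.06 and DDR2 by 1.25 ± 0.08. Genes under nitrogen catabolite repression fell in 17 of 27 cases and 1 rose, also adjusted over the list alone, with a median of -0.41 (camera adjusted p = 9.4e-07) and adjusted p = 0.11 with an estimated correlation. DAL4 fell by 1.44 ± 0.09, DAL7 by 1.24 ± 0.07, DAL5 by 1.16 ± 0.07 and the glutamate dehydrogenase gene GDH3 by 0.97 ± 0.08. Trehalose and glycogen genes fell in 14 of 20 cases, also adjusted over the list alone, with a median of -0.52 (camera adjusted p = 4.2e-08) and adjusted p = 0.27 with an estimated correlation. GPH1 fell by 0.77 ± 0.06 and the glycogen synthase gene GSY2 by 0.73 ± 0.07.

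Ribosome biogenesis genes rose in 61 of 100 cases and none fell in MDS3e MKT1e (68 adjusted over the list alone), led by RRP15 at 0.88 ± 0.09 and the GTPase gene NOG1 at 0.70 ± 0.08. Their median was 0.28 (camera adjusted p = 3e-10), with adjusted p = 0.37 with an estimated correlation. Iron regulon genes rose in 14 of 28 cases and none fell (17 adjusted over the list alone), among them the low-affinity iron transporter gene FET4 by 0.70 ± 0.07 and TIS11, whose product promotes decay of mRNAs in low iron, by 0.69 ± 0.09. Their median was 0.23 (camera adjusted p = 0.00063), with adjusted p = 0.23 with an estimated correlation. Vacuolar ATPase genes fell in 11 of 18 cases and none rose, also adjusted over the list alone, with VMA13 falling by 0.49 ± 0.07 and VMA1 by 0.45 ± 0.06, the latter at -0.27 after quantile normalization. Their median was -0.21 (camera adjusted p = 0.00045), with adjusted p = 0.23 with an estimated correlation. Cytosolic ribosomal protein genes fell in 88 of 127 cases and 3 rose (95 and 4 adjusted over the list alone), with a median of -0.26 that turned to 0.01 after quantile normalization (camera adjusted p = 9.5e-18, and adjusted p = 0.23 with an estimated correlation). The 545 brightest genes had a median of -0.20 in this comparison.

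YHB1 rose by 2.34 ± 0.08, CYC1 by 1.93 ± 0.08 and ARO9, an aromatic aminotransferase gene, by 1.29 ± 0.09 in MDS3e MKT1e. PTR2 fell by 1.59 ± 0.09, IMD2 by 1.45 ± 0.10 and ADH2 by 1.17 ± 0.07. In all 2107 genes changed, 1196 higher and 911 lower, 48 of them at least 2-fold, and after median centring 785 were higher and 1423 lower.

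The effect of each allele was then measured again with the other allele present. For each allele, the comparison in this background shared no arrays with the comparison of the same allele alone against ancestral, although the spread was pooled over all arrays. Where MDS3e was present, MKT1e was accompanied by rises of 71 of 73 mitochondrial ribosomal protein genes with none falling (72 and 1 adjusted over the list alone), with a median of 0.65. The camera adjusted p was 1.4e-54, and adjusted p = 0.0079 with an estimated correlation. MRPL4 rose by 1.12 ± 0.06. Other genes of mitochondrial translation among the largest rises were the elongation factor gene MEF1 by 1.02 ± 0.06, the tyrosyl-tRNA synthetase gene MSY1 by 1.06 ± 0.08 and the tRNA modification gene MTO1 by 1.02 ± 0.07. PET117, for cytochrome oxidase assembly, rose by 1.10 ± 0.09.

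In that same background, 17 of 38 respiratory chain genes rose and 1 fell (24 and 1 adjusted over the list alone), with a median of 0.23 (camera adjusted p = 1.5e-10) and adjusted p = 0.22 with an estimated correlation. CYC1 rose by 1.18 ± 0.08 and RIP1, the Rieske subunit of complex III, by 0.57 ± 0.06. Of 27 genes under nitrogen catabolite repression, 14 fell and 1 rose (14 and 2 adjusted over the list alone), with a median of -0.22 (camera adjusted p = 3e-07) and adjusted p = 0.11 with an estimated correlation. DAL5 fell by 1.25 ± 0.07, OPT2 by 1.25 ± 0.08, DAL4 by 1.02 ± 0.09 and DIP5 by 1.65 ± 0.18, and the phosphatase gene PHO5 rose by 0.89 ± 0.08. IMD2 fell by 1.86 ± 0.10 and ADH2 by 1.24 ± 0.07, while YRO2 rose by 1.94 ± 0.12 and YHB1 by 1.22 ± 0.08. In all 937 genes changed, 597 higher and 340 lower, 15 of them at least 2-fold, and after median centring 515 were higher and 489 lower. The count was 546 without MDS3e MKT1e replicate 1, 531 without MDS3e replicate 1 and 461 without MDS3e replicate 2.

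Across the 5449 genes, the MKT1e differences in the 2 backgrounds correlated with Pearson's r = 0.81 and Spearman's rho = 0.72, and the slope was 0.74. These are correlations across genes, which are not independent replicates. The slope is by least squares, and error in the differences against ancestral pulls it towards 0. It therefore cannot show by itself that the allele did less in the second background. The SD of the differences over all genes was 0.234 against ancestral and 0.213 where MDS3e was present. Of the genes called in both, 435 were higher in both against 70.3 for independent lists, 203 were lower in both against 28.8, and 3 were opposite.

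Where MKT1e was present, MDS3e was accompanied by rises of 14 of 18 phosphate regulon genes with 1 falling (15 and 1 adjusted over the list alone). PHO89 rose by 2.79 ± 0.10, PHO5 by 2.44 ± 0.08, PHM6 by 2.17 ± 0.11 and VTC3 by 1.76 ± 0.08. Their median was 0.96 (camera adjusted p = 3.8e-12), with adjusted p = 0.22 with an estimated correlation. General stress genes fell in 39 of 51 cases and none rose (42 adjusted over the list alone), with a median of -0.65 (camera adjusted p = 1.1e-28) and adjusted p = 0.15 with an estimated correlation. DDR2, HXT5, CTT1 and YGP1 fell by 1.69 ± 0.08, 1.67 ± 0.08, 1.63 ± 0.09 and 1.57 ± 0.08. Of 20 trehalose and glycogen genes, 12 fell and 1 rose, also adjusted over the list alone, with a median of -0.35 (camera adjusted p = 1.9e-07) and adjusted p = 0.28 with an estimated correlation. The trehalose genes TSL1 and TPS2 fell by 0.77 ± 0.07 and 0.70 ± 0.06.

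Ribosome biogenesis genes rose in 38 of 100 cases with none falling in that background (45 adjusted over the list alone), with a median of 0.20 (camera adjusted p = 7e-07) and adjusted p = 0.48 with an estimated correlation. RRP15 rose by 0.62 ± 0.09 and RPC40, a subunit of RNA polymerases I and III, by 0.60 ± 0.09. The cytosolic ribosomal protein median of -0.27 turned to 0.03 after quantile normalization, with 76 of 127 genes falling and 2 rising before it (92 and 3 adjusted over the list alone, camera adjusted p = 7.1e-21, adjusted p = 0.23 with an estimated correlation). The histone median of -0.16 turned to 0.03 after quantile normalization and to 0.01 after cyclic loess, with 4 of 9 genes falling before it, also adjusted over the list alone (camera adjusted p = 0.027, adjusted p = 0.23 with an estimated correlation). The 545 brightest genes had a median of -0.17 here. TKL2 fell by 1.97 ± 0.09, FMP16 by 2.03 ± 0.08 and the proline permease gene PUT4 by 1.10 ± 0.11, and HXT2 and the ethyl ester synthase gene EEB1 rose by 1.39 ± 0.15 and 1.54 ± 0.12. In all 1440 genes changed, 815 higher and 625 lower, 48 of them at least 2-fold, against 465 higher and 912 lower after median centring and 497 and 595 after cyclic loess. The count was 893 without MDS3e MKT1e replicate 1, 700 without MDS3e MKT1e replicate 2 and 543 without MKT1e replicate 2.

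Between the 2 backgrounds, the MDS3e differences correlated across genes with Pearson's r = 0.84 and Spearman's rho = 0.77, with a slope of 0.93. The same limit holds for this slope, and the SD of the differences was 0.227 against ancestral and 0.252 where MKT1e was present. Of the genes called in both, 472 were higher in both against 118 for independent lists, 421 were lower in both against 67.1, and 3 were opposite.

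**Figure D2:**
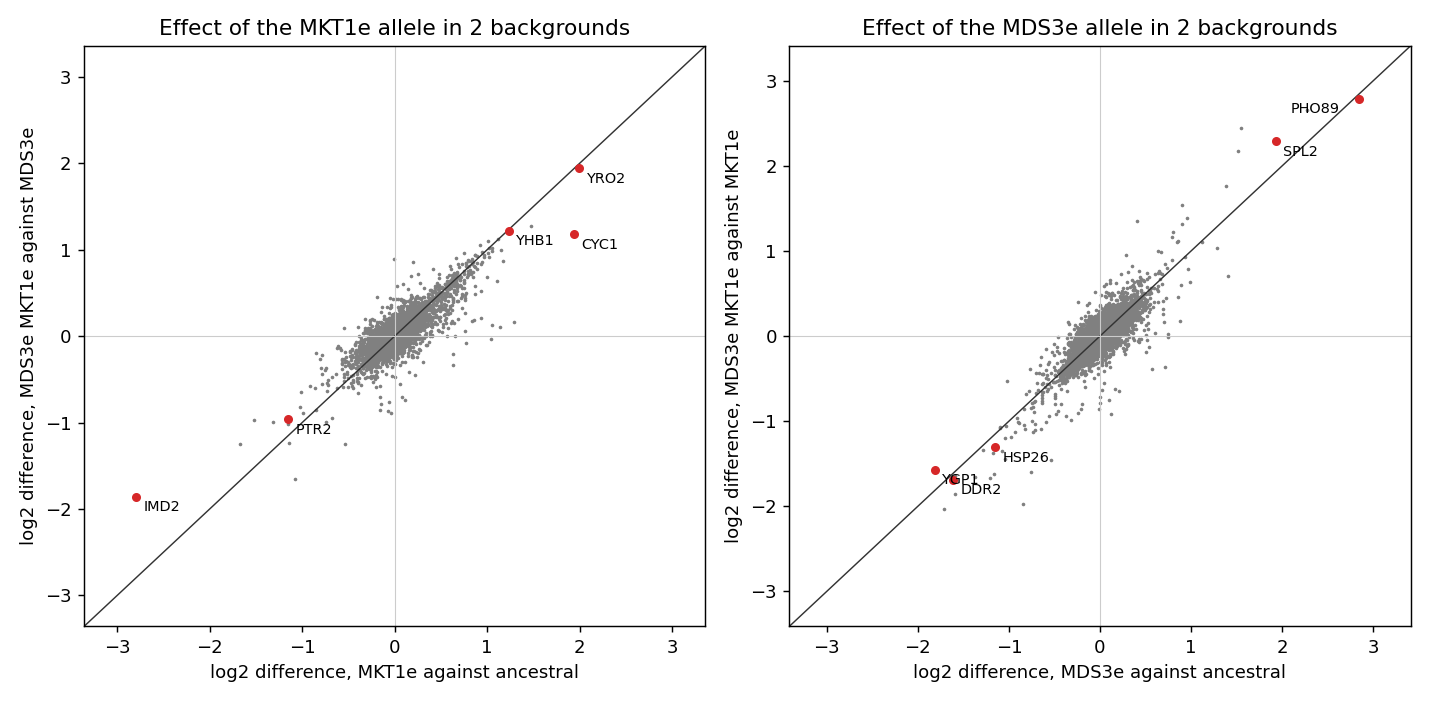
Log2 difference of each of 5449 genes with an evolved allele added to the ancestral strain (horizontal axis) against the log2 difference with it added where the other evolved allele was present (vertical axis), for MKT1e and for MDS3e, each point a gene and each value from 2 arrays per genotype. The line marks equal differences, and the fitted slopes, not drawn, were 0.74 and 0.93, with Pearson's r of 0.81 and 0.84 across genes.

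Departure from additivity of the 2 alleles was tested as an interaction on the log2 scale. It was called for 21 genes, 4 above and 17 below the additive value, and 387 genes had an unadjusted p under 0.05. A share of 0.05 of the 5449 genes would be expected there without any departure. After median centring 25 genes were called, 4 above and 21 below. TKL2 lay at -1.13 ± 0.13 (adjusted p = 0.0033): its mean log2 level was 5.31 in ancestral cells, 6.60 in MKT1e, 4.47 in MDS3e and 4.63 in MDS3e MKT1e. The last 2 are dim, where the added 16 shrinks differences, and with pseudocount 1 the value was -1.28 (adjusted p = 0.043). PHO5 lay above additivity at 0.90 ± 0.11 (adjusted p = 0.005), and AIF1, an apoptosis-inducing factor gene, below it at -0.70 ± 0.09 (adjusted p = 0.0048). YGR109W-A, a retrotransposon reading frame with a shared probe set, lay at -1.03 ± 0.10 (adjusted p = 0.0014). Of the 21, 7 lay close together on chromosome III and are described with that chromosome. The phosphate regulon list had a median interaction of 0.32 (camera adjusted p = 7.6e-09), with adjusted p = 0.23 with an estimated correlation; 1 of 18 members passed, and 7 adjusted over the list alone. YHB1 lay at -0.02, after rises of 1.24 with MKT1e, 1.12 with MDS3e and 2.34 with both. The count was 13 without MDS3e MKT1e replicate 2 and 13 without MDS3e replicate 2.

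In PMA1e MKT1e against ancestral, 70 of 73 mitochondrial ribosomal protein genes rose and none fell (72 adjusted over the list alone), with a median of 0.67. The camera adjusted p was 8.3e-47, and adjusted p = 0.0079 with an estimated correlation. MRPL4 rose by 1.21 ± 0.06. Respiratory chain genes rose in 20 of 38 cases and 1 fell (27 and 1 adjusted over the list alone), with a median of 0.28 (camera adjusted p = 2.5e-10) and adjusted p = 0.22 with an estimated correlation, and CYC1 rose by 1.84 ± 0.08 and NDI1 by 0.96 ± 0.08. General stress genes rose in 27 of 51 cases and 2 fell (27 and 3 adjusted over the list alone), with a median of 0.26 (camera adjusted p = 2.1e-07) and adjusted p = 0.3 with an estimated correlation. HSP26 rose by 1.44 ± 0.12, SIP18 by 1.43 ± 0.13 and CTT1 by 1.35 ± 0.09.

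Genes under nitrogen catabolite repression fell in 13 of 27 cases and 3 rose in PMA1e MKT1e (15 and 4 adjusted over the list alone), with a median of -0.21 (camera adjusted p = 1.4e-05) and adjusted p = 0.15 with an estimated correlation. DAL5 fell by 1.30 ± 0.07, DAL7 by 0.98 ± 0.07 and ASP3-1, an asparaginase gene with a probe set shared among copies, by 1.17 ± 0.07. The amino acid permease genes DIP5 and GNP1 fell by 1.43 ± 0.18 and 1.05 ± 0.18, and GNP1 stood at -0.68 (adjusted p = 0.0015) without PMA1e MKT1e replicate 2. Amino acid biosynthesis genes fell in 15 of 58 cases and 2 rose (16 and 2 adjusted over the list alone), with a median of -0.09 (camera adjusted p = 4.2e-05) and adjusted p = 0.31 with an estimated correlation, and the call was also lost after quantile normalization. The branched-chain aminotransferase genes BAT2 and BAT1 fell by 0.51 ± 0.09 and 0.47 ± 0.06. YRO2 rose by 2.57 ± 0.12, TKL2 by 1.66 ± 0.09, YHB1 by 1.34 ± 0.08 and AGX1, an alanine and glyoxylate aminotransferase gene, by 1.19 ± 0.12. IMD2 fell by 2.66 ± 0.10 and HXT2 by 1.43 ± 0.15. In all 1177 genes changed, 778 higher and 399 lower, 29 of them at least 2-fold. After median centring 587 were higher and 782 lower, and after quantile normalization 641 and 582. The count was 751 without PMA1e MKT1e replicate 1 and 622 without PMA1e MKT1e replicate 2.

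The contribution of the PMA1 allele was measured where MKT1e was present, as PMA1e MKT1e against MKT1e. With limma 1 gene was called, also after median centring, and 537 had an unadjusted p under 0.05. A share of 0.05 of the 5449 genes would be expected there without any difference. By brightness, group medians ran from 0.05 in the second dimmest of 10 groups to -0.05 in the brightest. How much this trend adds to the 537 was not tested. The gene called was BAT1, the mitochondrial branched-chain aminotransferase, which fell by 0.54 ± 0.06 (adjusted p = 0.031). Its call was lost in 7 of the 10 runs that left out an array and stayed only without Ancestral replicate 1, Ancestral replicate 2 or PMA1e MKT1e replicate 1, and the highest adjusted p was 0.36, without PMA1e MKT1e replicate 2. The number of genes called was 4 without Ancestral replicate 1, 4 without Ancestral replicate 2, 11 without PMA1e MKT1e replicate 1 and 0 without any 1 of the other 7 arrays. The median half-width of the 95% interval was 0.15 (1.11-fold), 9 genes had a difference of at least 0.5 in size, and the largest was 0.81 in size.

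Several lists had small medians that camera called in PMA1e MKT1e against MKT1e, with no single member past the test other than BAT1. General stress genes had a median of 0.13 (camera adjusted p = 6.5e-10), with adjusted p = 0.24 with an estimated correlation and 5 of 51 members past the test adjusted over the list alone. Its largest members were HSP30, a stress protein of the plasma membrane, at 0.46 ± 0.07 (adjusted p = 0.073) and the peroxidase gene GPX1 at 0.41 ± 0.10 (adjusted p = 0.19). HSP30 passed the test without Ancestral replicate 1 or without Ancestral replicate 2, with adjusted p = 0.025 each time. Genes under nitrogen catabolite repression had a median of 0.10 (camera adjusted p = 0.00051), with adjusted p = 0.19 with an estimated correlation, and adjusted over the list alone 10 rose and 1 fell. Ribosome biogenesis genes had a median of -0.08 (camera adjusted p = 2.8e-13), with adjusted p = 0.32 with an estimated correlation. Pheromone response genes had a median of -0.04 (camera adjusted p = 0.00024), with adjusted p = 0.15 with an estimated correlation.

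The 2 strains that share MKT1e were also set against each other, with PMA1e MKT1e over MDS3e MKT1e. General stress genes were higher in PMA1e MKT1e in 45 of 51 cases and lower in none (45 and 1 adjusted over the list alone), with a median of 0.79 (camera adjusted p = 3.3e-29) and adjusted p = 0.15 with an estimated correlation. CTT1 was higher by 1.88 ± 0.09, SIP18 by 1.83 ± 0.13, HXT5 by 1.78 ± 0.08 and DDR2 by 1.70 ± 0.08. Phosphate regulon genes were lower in 14 of 18 cases and higher in 1 (15 and 1 adjusted over the list alone), with a median of -0.92 (camera adjusted p = 1.5e-10) and adjusted p = 0.23 with an estimated correlation. The differences were -3.33 ± 0.10 for PHO89, -2.02 ± 0.08 for PHO5 and -1.90 ± 0.11 for PHM6, and 2.05 ± 0.09 for PHM7. Trehalose and glycogen genes were higher in 14 of 20 cases and lower in 1, also adjusted over the list alone, with a median of 0.44 (camera adjusted p = 7.6e-09) and adjusted p = 0.24 with an estimated correlation.

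Ribosome biogenesis genes were lower in PMA1e MKT1e than in MDS3e MKT1e in 63 of 100 cases and higher in none (71 adjusted over the list alone), with a median of -0.27 (camera adjusted p = 4e-14) and adjusted p = 0.31 with an estimated correlation. Genes of gluconeogenesis and non-fermentable carbon use were higher in 12 of 23 cases (12 and 1 adjusted over the list alone), with a median of 0.21 (camera adjusted p = 0.00051) and adjusted p = 0.15 with an estimated correlation. They included the cytosolic malate dehydrogenase gene MDH2 by 0.67 ± 0.07 and the mitochondrial glycerol-3-phosphate dehydrogenase gene GUT2 by 0.61 ± 0.08. The cytosolic ribosomal protein median of 0.19 turned to -0.04 after quantile normalization (camera adjusted p = 1.4e-08, adjusted p = 0.33 with an estimated correlation), with 62 of 127 genes higher and 5 lower before it (71 and 6 adjusted over the list alone), and the 545 brightest genes had a median of 0.14. TKL2 was higher by 2.34 ± 0.09, FMP16 by 2.20 ± 0.08, the transaldolase gene NQM1 by 1.95 ± 0.14 and the cell wall gene PIR3 by 1.46 ± 0.08. HXT2 stood at -2.02 ± 0.15 and IMD2 at -1.21 ± 0.10. In all 1709 genes differed, 831 higher and 878 lower, 58 of them at least 2-fold, and after median centring 929 were higher and 738 lower. The count was 928 without MDS3e MKT1e replicate 2, 970 without PMA1e MKT1e replicate 1 and 801 without PMA1e MKT1e replicate 2.

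Chromosome by chromosome, the largest shift of a median against all genes was -0.05, for chromosome III in MDS3e MKT1e against ancestral, and camera called no chromosome in any comparison. Medians over windows of 9 neighbouring genes, in the gene order of the R64 assembly, reached 0.5 in size only on chromosome III and only in comparisons with MDS3e MKT1e. The 11 genes from MAK32 to RHB1 were singled out there after their values were seen. All 11 were lower in MDS3e MKT1e than in MKT1e, 9 of them past the test, with a median of -0.71. Against MDS3e the median was -0.74 and against ancestral -0.69. PET18 fell by 1.00, NPP1, a nucleotide pyrophosphatase gene, by 0.86, YCR023C by 0.77, MAK31 by 0.69, RHB1, a Ras-like GTPase gene, by 0.64 and MAK32 by 0.54 against ancestral. MAK31 and MAK32 are known for the propagation of a double-stranded RNA virus of yeast.

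The ratio of mean intensity in MDS3e MKT1e over MKT1e ran from 0.338 for HSP30 to 0.901 for PMP1 across these 11 genes, with a median of 0.589. The neighbours on either side, SRD1 and FEN2, differed by -0.05 and 0.12 from MKT1e. Against ancestral, however, SRD1 fell by 0.38 (adjusted p = 0.0087), and SLM5 inside the segment differed by only -0.09 (adjusted p = 0.22). The mean intensity of SLM5 was 162 in ancestral, 161 in MDS3e, 288 in MKT1e, 285 in PMA1e MKT1e and 152 in MDS3e MKT1e. Its difference of MDS3e MKT1e from MKT1e was -0.86, which offset the rise with MKT1e. The segment's median differed by -0.06 in MKT1e and by 0.01 in MDS3e from ancestral. Interaction values were -0.85 ± 0.08 for MAK31, -0.84 ± 0.10 for RHB1, -0.84 ± 0.08 for SLM5, a mitochondrial asparaginyl-tRNA synthetase gene, -0.79 ± 0.08 for NPP1, -0.78 ± 0.08 for MAK32, -0.71 ± 0.09 for YCR023C and -0.64 ± 0.07 for PET18, each past the test.

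**Figure D3:**
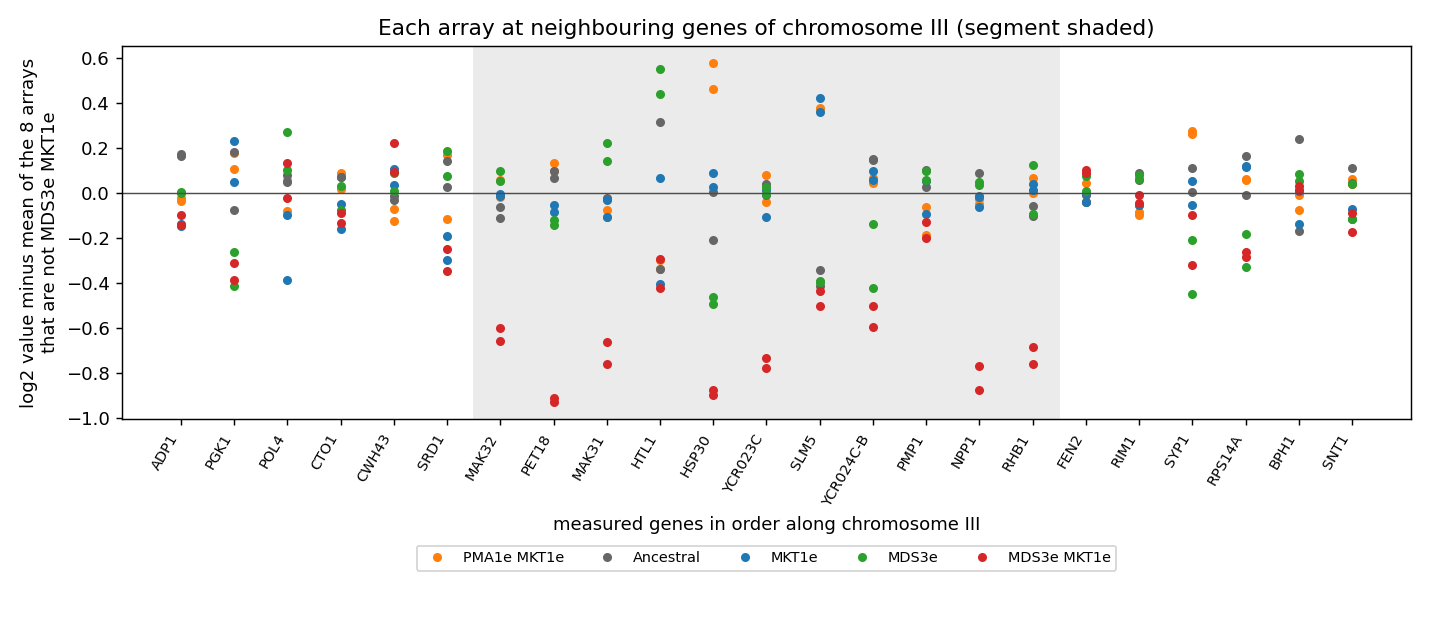
Log2 value of each of the 10 arrays minus the mean of the 8 arrays that are not MDS3e MKT1e (vertical axis) at genes in order along chromosome III (horizontal axis), with the 11 genes from MAK32 to RHB1 shaded. Both MDS3e MKT1e arrays lie lowest at most shaded genes, such as PET18 at -0.93 and -0.91, while at FEN2 they lie at 0.09 and 0.10.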

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

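The genes, lists and probe sets given first below were taken by rules fixed in advance. The patterns weighed in the last 3 paragraphs, and the tests of their causes, were all chosen after the results were seen.

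The interaction of MDS3e and MKT1e was called for 21 genes. Below additivity lay TKL2 at -1.13, PAU4 at -1.08, YGR109W-A at -1.03, YLL066W-B at -0.96, MAK31 at -0.85, RHB1 at -0.84, SLM5 at -0.84, NPP1 at -0.79, MAK32 at -0.78, CYC1 at -0.76, PAU18 at -0.72, YCR023C at -0.71, OPT2 at -0.71, AIF1 at -0.70, PET18 at -0.64, YNL195C at -0.60 and ENT4 at -0.56. Above it lay ANB1 at 0.45, PLB2 at 0.56, PHO5 at 0.90 and IMD2 at 0.94. The calls of ANB1, PAU4, YNL195C, OPT2, PLB2, CYC1, ENT4, PAU18 and IMD2 were lost when some arrays were left out. PAU4, PAU18, YGR109W-A, YLL066W-B and IMD2 have shared probe sets. MAK32, PET18, MAK31, YCR023C, SLM5, NPP1 and RHB1 belong to the segment of chromosome III.

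Camera called the interaction for 8 gene lists, with medians of -0.0635 for the respiratory chain and ATP synthase, -0.0394 for cytosolic ribosomal proteins, -0.0460 for ribosome biogenesis, -0.0558 for general stress, 0.32 for the phosphate regulon, 0.15 for the iron regulon, -0.11 for a-specific and alpha-specific genes and -0.15 for pheromone response. With an estimated correlation none was called, and the adjusted p values in the same order were 0.33, 0.7, 0.71, 0.5, 0.23, 0.21, 0.19 and 0.097. Leaving out 1 array ended 3 of the calls and moved 2 of those medians past 0. General stress stood at -0.0355 (adjusted p = 0.12) without Ancestral replicate 1, 0.00229 (0.062) without MKT1e replicate 2 and 0.0195 (0.36) without MDS3e MKT1e replicate 2. Ribosome biogenesis stood at 0.00727 (adjusted p = 0.71) without Ancestral replicate 2, -0.00264 (0.71) without MKT1e replicate 1, -0.0368 (0.088) without MDS3e replicate 1 and -0.00191 (0.55) without MDS3e MKT1e replicate 1. Cytosolic ribosomal proteins stood at -0.00594 (adjusted p = 0.95) without Ancestral replicate 1, -0.0120 (0.53) without MKT1e replicate 2, -0.000486 (0.95) without MDS3e replicate 2 and -0.0179 (0.18) without MDS3e MKT1e replicate 2.

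Probe sets without a gene entry, 3517 without the Affymetrix controls and 426 of them above background, were tested with limma apart from the genes. The number called was 31 in MKT1e, 35 in MDS3e, 45 in MDS3e MKT1e and 20 in PMA1e MKT1e against ancestral. It was 15 for MDS3e MKT1e against MDS3e, 21 for MDS3e MKT1e against MKT1e, 1 for PMA1e MKT1e against MKT1e, 41 for PMA1e MKT1e against MDS3e MKT1e and 2 for the interaction. Which transcripts they read was not worked out. Of the 1746 probe sets of another species, limma called 0 in every comparison, with 92 to 115 at an unadjusted p under 0.05.

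The first pattern weighed was the fall of 11 neighbouring genes of chromosome III in MDS3e MKT1e, with a median of -0.71 against MKT1e. Cyclic loess gave -0.79, which excludes scaling by brightness, and the higher of the 2 arrays lay at -0.52 while the lowest of the other 8 lay at 0.09, which excludes 1 odd array. In 1000 shuffles of the gene order the lowest median of a window of 11 genes was -0.41 (permutation p = 0.001, the smallest possible). This argues against independent changes of neighbours, although the window width was taken from the segment after its values were seen. Fewer DNA copies of the segment in that strain could give such a fall. The SD of the segment's differences stood at percentile 79.0 of 5268 other windows, so its genes varied more than in most windows but not beyond their range. That test cannot tell fewer copies from another local fall. In these haploid strains, loss of the only copy in every cell is excluded. The lowest intensity of the 11 genes on the MDS3e MKT1e arrays was 14.1 against a background limit of 1.73. A fall from 2 copies to 1 would need more than 1 copy in the other haploid strains. That, or a loss in part of the culture, stays open without DNA data, and so these genes cannot be read as an interaction of the 2 alleles.

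The second pattern was the fall of cytosolic ribosomal protein mRNAs, by 0.23 in MDS3e and by 0.26 in MDS3e MKT1e on the log2 scale, which vanished after quantile normalization. The list minus the cre control probe sets, which carry no yeast sequence, was -0.19 in MDS3e and -0.11 in MDS3e MKT1e. These probe sets were dimmer on average than the list, at 10.67 against 10.88. There were only 6 of them, and they moved unequally, by -0.05 and -0.17, where the list moved by similar amounts. They therefore cannot show how much of the fall is compression of bright signals on the array. The list minus 189 genes matched on mean level was -0.0366 and -0.0292, which fits a fall shared by bright mRNAs of other functions, but those genes were dimmer on average, at 10.50 against 10.88; against the 5 nearest genes of each, at 10.88 with repeats, the list fell less, by 0.0387 and 0.0400, so nothing specific to ribosomal proteins can be claimed. The first 2 tests were first run under other names, with the matched genes read as a test of compression, and were paired with their present explanations after the values were seen, which did not change.

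The third pattern was the rise of mitochondrial ribosomal protein mRNAs with MKT1e. Its median of 0.66 was 0.68 after cyclic loess, and the lowest of the 6 arrays with the allele lay 0.58 above the highest of the 4 without, so neither scaling nor 1 array explains it. The list also rose by 0.42 more than 54 genes of the respiratory chain and the tricarboxylic acid cycle. The permutation p was 1e-05, the smallest possible, but the shuffles treated genes read on the same arrays as independent. The compared lists were brighter, with median levels of 10.19 and 9.87 against 8.58. An equal rise of all nuclear genes for mitochondrial proteins was therefore not seen. Whether bright probe sets respond less was not tested. A biological cause is thus a hypothesis: the evolved allele might act on a regulator shared by these mRNAs, such as the RNA-binding protein Puf3, which is known to bind many of them. Neither Puf3 binding nor mRNA decay was measured here.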

How the results depend on the processing

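Most settings below were fixed beforehand, while cyclic loess, exchanged replicate numbers, lists with an array left out and 2-fold counts with other pseudocounts were chosen after results had been seen; the cause of each move was not tested unless stated.

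Stricter thresholds lowered every count by construction. At adjusted p under 0.01, and then at 2-fold, the count was 581 and 29 in MKT1e, 549 and 27 in MDS3e, 1255 and 48 in MDS3e MKT1e and 656 and 29 in PMA1e MKT1e against ancestral. It was 475 and 15 for MDS3e MKT1e against MDS3e, 612 and 48 against MKT1e, 0 and 0 for PMA1e MKT1e against MKT1e, where limma had 537 genes at an unadjusted p under 0.05, 832 and 58 for PMA1e MKT1e against MDS3e MKT1e, 12 and 3 for the interaction and 1938 and 102 for the F-test. With only the compared genotypes fitted, counts against ancestral were 578 in MKT1e, 790 in MDS3e, 1468 in MDS3e MKT1e and 823 in PMA1e MKT1e. They were 942 for MDS3e MKT1e against MDS3e, 1318 against MKT1e and 1862 for PMA1e MKT1e against MDS3e MKT1e. Array weights gave 784, 1036, 1713 and 976 against ancestral in the same order, and 1088, 1499 and 2017 for the other comparisons just named. PMA1e MKT1e against MKT1e gave 0 with only the compared genotypes and 8 with array weights. It gave 2 with trended and robust variances, 2 after quantile normalization, 2 after cyclic loess and 0 with pseudocount 1. The 2-fold counts, in the order above without the F-test, were 49, 51, 90, 59, 34, 75, 0, 92 and 8 with pseudocount 1 and 9, 12, 20, 11, 6, 22, 0, 32 and 0 with pseudocount 64.

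With 1 array left out, the counts ran from 676 to 1217 in MKT1e, from 554 to 1437 in MDS3e, from 1455 to 2068 in MDS3e MKT1e and from 622 to 1201 in PMA1e MKT1e against ancestral. They ran from 461 to 1088 for MDS3e MKT1e against MDS3e, from 543 to 1700 against MKT1e, from 0 to 11 for PMA1e MKT1e against MKT1e, from 801 to 1943 for PMA1e MKT1e against MDS3e MKT1e, from 13 to 24 for the interaction and from 2435 to 3136 for the F-test. The number of gene lists called ran, in the same order of comparisons, from 8 to 15, 11 to 14, 14 to 18, 9 to 16, 7 to 10, 15 to 16, 10 to 16, 11 to 15 and 7 to 10. The median interaction of cytosolic ribosomal proteins ran from -0.0734 to -0.000486 and kept its sign, though camera's direction changed without MDS3e replicate 2. That of glycolysis ran from -0.110 to 0.0395 and turned without Ancestral replicate 1.

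The replicate numbers are shared among genotypes. Deviations of equal numbers correlated by 0.39, 0.24 and 0.19 among Ancestral, MKT1e and MDS3e, by -0.14 to -0.20 between MDS3e MKT1e and each other genotype, and by 0.02, 0.03 and -0.01 between PMA1e MKT1e and those 3. The design fixed beforehand did not pair the arrays, and these correlations, computed later, were not all positive. A batch shared by some of the arrays, with the numbers of MDS3e MKT1e exchanged, stays open. A replicate block gave 1105 genes in MKT1e, 1384 in MDS3e, 2115 in MDS3e MKT1e and 2 for PMA1e MKT1e against MKT1e, and moved no other count of genes by over 1.5 times. With the numbers of MDS3e MKT1e exchanged, a pairing picked from the same correlations, the block kept every call and gave 1377 genes in MKT1e, 1632 in MDS3e, 2330 in MDS3e MKT1e and 1372 in PMA1e MKT1e against ancestral, 1128 for MDS3e MKT1e against MDS3e, 1707 against MKT1e, 4 for PMA1e MKT1e against MKT1e, 1958 against MDS3e MKT1e and 34 for the interaction.

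With an estimated correlation between genes, camera called 1 list instead of 10 in MKT1e, 0 of 13 in MDS3e, 1 of 18 in MDS3e MKT1e and 1 of 12 in PMA1e MKT1e against ancestral. It called 1 of 9 for MDS3e MKT1e against MDS3e, 0 of 16 against MKT1e, 0 of 15 for PMA1e MKT1e against MKT1e, 0 of 14 against MDS3e MKT1e and 0 of 8 for the interaction. With fry the number was 13 in MKT1e, 16 in MDS3e, 19 in MDS3e MKT1e and 18 in PMA1e MKT1e against ancestral. It was 14 for MDS3e MKT1e against MDS3e and 18 against MKT1e. For PMA1e MKT1e it was 5 against MKT1e and 21 against MDS3e MKT1e, and for the interaction it was 4.

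Quantile normalization left 6 lists called in MDS3e, 9 in MDS3e MKT1e and 7 in PMA1e MKT1e against ancestral, 8 for MDS3e MKT1e against MKT1e, 7 for PMA1e MKT1e against MKT1e and 7 against MDS3e MKT1e. It turned camera's direction for cytosolic ribosomal proteins in MDS3e (-0.00578), in MDS3e MKT1e against ancestral (0.0124), MDS3e (-0.00387) and MKT1e (0.0310), in PMA1e MKT1e against MDS3e MKT1e (-0.0397) and in the interaction (0.00599). It also turned that of histones in MDS3e MKT1e against MKT1e (0.0265), and glycolysis (0.0253) and the respiratory chain (0.0108) in PMA1e MKT1e against MKT1e. Single genes turned were MFA2 in MDS3e MKT1e against ancestral (0.000502) and STE2 (0.00237), HTA2 (0.0114, shared probe set) and HTB1 (0.0265) against MKT1e.

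Cyclic loess left 6 lists called in MDS3e and 11 in MDS3e MKT1e against ancestral, 9 for MDS3e MKT1e against MKT1e, 9 for PMA1e MKT1e against MKT1e and 8 against MDS3e MKT1e. It turned camera's direction for amino acid biosynthesis in MDS3e MKT1e against ancestral (0.0732), histones against MKT1e (0.0109), glycolysis (0.0425) and the respiratory chain (0.0159) in PMA1e MKT1e against MKT1e, and cytosolic ribosomal proteins in PMA1e MKT1e against MDS3e MKT1e (0.00138) and in the interaction (0.000787). MFA2 in MDS3e MKT1e against ancestral (0.0118) and HTB1 against MKT1e (0.0109) turned as well. The values in parentheses are medians, which can keep their sign where camera's direction turns.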

Other observations

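All genes in this part were chosen after their values were seen.

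URA3 lay between 4.01 and 4.08 in all strains, below the background limit of 4.15. The medium contained uracil, but whether that accounts for the low value was not tested.

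YHB1 had a mean log2 level of 7.77 in ancestral cells, 9.01 in MKT1e, 8.89 in MDS3e, 10.11 in MDS3e MKT1e and 9.11 in PMA1e MKT1e, so the rises with the 2 alleles added up on the log2 scale.

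A nuclear gene for a mitochondrial protein outside the ribosome and the respiratory chain moved with MKT1e too. COX10, for haem a synthesis, differed from ancestral by 1.01 in MKT1e, by 0.05 in MDS3e and by 1.02 in MDS3e MKT1e.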
